A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

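Total RNA of BY4743 cultures grown with 0 or 40 g/l isopropanol was labelled with Cyanine 3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. Samples were assigned to the control (n = 4) and isopropanol (n = 4) groups from their titles, which also number the replicates. Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 9.5.3.1 (the submitters' processing notes name version 9), and their processed signal is an intensity after background subtraction and detrending, with no scaling between arrays. The median signal and local background columns are raw intensity values, per the file headers. The deposited series matrix holds log2 values of the same arrays. Set against the scanner values it was log2 signal relative to each array's 75th percentile (median between -1.52 and -1.32 over arrays, rank correlation of 0.999 to 1 over 6256 probes), with its direction the same, no centring of genes, and its remaining processing not given in the sources used here. Flags for background, uniformity and saturation were other columns of the files deposited by the authors, and 0 spots were saturated.

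Processed signal was taken to log2 and each array's 75th percentile over its yeast spots was subtracted. Spots flagged as non-uniform or as population outliers (0 to 21 per array) and all control spots were left out, and the 2 spots of each probe were averaged. A probe was kept where it was well above background on every array of at least 1 group. The brightest probe stood for a gene: 28 genes had several probes, and for 24 of them several were measured on all arrays, with 0 in which probes moved apart in direction by over 0.2 log2 to each side. Scanner files name probes by systematic name, of an older genome annotation (sacCer1). Of 6256 probes, 5765 matched a locus tag of the RefSeq gene table (assembly R64), which gave symbols, and 491 kept the file's name. No coordinates are printed, since the builds differ. Array number limits the precision: each group has 4 arrays.

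Differences were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with Benjamini-Hochberg adjustment over 5816 genes, at an adjusted p of 0.05 and, for the stricter count, a log2 change of at least 1. Where no array of a group was well above background, the change is a lower bound: the mean of the brighter group against the mean, per array, of the higher of the probe's own signal and the lowest signal among probes well above background. For FIG1, measured on 1 control array, the other control arrays were treated in that way, a choice made after its values were seen. Adjusted p-values printed beside these bounds test the fitted change, not the bound. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the 37 lists of at least 5 tested members. The lists covered ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, mitochondrial ribosomes, histones, G1/S, G2/M, heat shock chaperones, general stress, trehalose and glycogen, proteasome, ubiquitin, autophagy, antioxidants, endoplasmic reticulum folding, multidrug resistance, cell wall, ergosterol, fatty acids, phospholipids, vacuolar ATPase, Gcn4-type amino acid, aromatic amino acid, sulfur, nitrogen, gluconeogenesis, tricarboxylic acid cycle, respiration, hexose transport, glycolysis, alcohol and aldehyde dehydrogenases, osmotic, peroxisomal oxidation, sporulation, haploid mating, iron and phosphate genes. Of their members 2 matched no locus tag and 4 were not on the array. Random lists for comparison (10000 per list) were matched on mean signal in 20 bins.

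Genes named in the text are the 12 increases and 12 decreases with the largest fitted changes among genes with a symbol that passed the test, whose groups did not overlap and that were well above background on all arrays of the brighter group. Of the 12 increases 6 have only a bound and FIG1 is given as one, and some of these bounds lie below the changes of genes named from the lists, such as ARG1 and PIR3, so the 12 are no ranking. Up to 4 members per described list with the largest change among those that passed, and the strain check genes, were named too. The rule itself was fixed in advance, but the 24 described lists were picked from the 37 after their results had been seen. The remaining 13 are given by counts and tests alone. The fit was tested on simulated data. With the spreads of these 5816 genes and 200 changed genes, the fit recovered 72.0% of 1.2-fold, 96.0% of 1.5-fold and 100% of 2-fold and 4-fold changes, with 7 false calls (3.66% of calls). In a further draw, where 1 list alone was shifted by design, camera called it and 0 of 36 other lists. The simulated noise was independent between genes, whereas the estimated inter-gene correlation was 0.399 for histones and 0.19 for heat shock chaperones. In the data 77.8% of genes changed, far more than were simulated. The simulation thus does not show how often camera calls lists falsely here. Alternatives were quantile normalization, median centring, normexp background correction (offset 50, on the median signal since the files used here hold no mean signal column), the series matrix, other filters on dim probes, flagged spots kept, the mean of probes, replicate and scan blocks, trended robust moderation, adjusted p under 0.01, a 1.5-fold minimum, treat against 1.5-fold, fry, an estimated correlation, and each array left out. Spike-in scaling and leaving out control replicate 3 with isopropanol replicate 1 were added after seeing the data. Ranges, lowest and highest values of a list's adjusted p over alternatives are those of camera at its preset correlation. They include these added settings and leave out fry and an estimated correlation. Figures were drawn with matplotlib 3.10.9.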

Results

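Gene expression was measured in the yeast Saccharomyces cerevisiae strain BY4743, a diploid laboratory strain, after 3 h in rich YPD medium with or without isopropanol (2-propanol). The labels give 4 arrays without isopropanol (control) and 4 arrays with 40 g/l isopropanol, all from 120 ml cultures shaken at 130 rpm and 30 °C. The descriptions of the isopropanol samples write the dose as 40 mg/l. Their source names, their characteristics and the series design give 40 g/l, which is used here. The design also names a 20 g/l culture, which is not analysed here. The series title names genes involved in tolerance to isopropanol, and the comparison asks which transcripts differed between treated and untreated cultures.

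Each 1-colour array held 6256 yeast probes on 12512 spots. The 75th percentile of processed signal was 1568 ± 172 (SD, n = 4) intensity units on the control arrays and 2260 ± 306 (SD, n = 4) on the isopropanol arrays. On the control arrays 92.9 ± 0.65% of spots (SD, n = 4) were well above background, against 94.98 ± 1.01% (SD, n = 4) on the isopropanol arrays. Arrays correlated at 0.996 to 0.999 within the isopropanol group, at 0.998 within the control group and at 0.963 to 0.969 across groups, over genes, which are not independent replicates. The series design speaks of independent experiments, but no label says which array came from which culture. The p-values therefore measure only the spread between these arrays, which may be technical. The median SD between arrays was 0.06 (control) and 0.08 (isopropanol) on the log2 scale, while duplicate spots alone give an SD of 0.05 for a 2-spot mean. All 4 control arrays lay on slide 1 and all 4 isopropanol arrays on slide 2, so slide and treatment cannot be told apart in any comparison. Control replicate 3 was scanned apart from the rest of its slide. LEU2 (YCL018W) and URA3 (YEL021W), which BY4743 lacks, served as a check of the strain. URA3 was above background in 0 of 16 spot readings and LEU2 in 1 of 16, on control replicate 3.

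Isopropanol went with a broad change in transcript levels. Of 5816 genes tested, 4525 (77.8%) changed, 2796 of them higher and 1729 lower (limma, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were seen in 551 genes, 436 higher and 115 lower, and 1119 of the 4525 changed by less than 1.2-fold. Of the 5816 genes, 4264 (73.3%) had groups that did not overlap, where chance gives 2.86%. The median log2 change over all genes was 0.11 on the scale of the 75th percentile, -0.02 after quantile normalization and -0.05 after median centring. The share of changed genes that were higher was 61.8% on the reported scale, 48.2% after quantile normalization, 45.2% after median centring and 43.2% with normexp background correction. Among the 2-fold genes that share was 79.1%, against 62.7%, 66.2% and 46.4%. On the reported scale changes also followed signal: the median was 0.54 over the 582 genes of lowest mean signal and -0.28 over the 582 of highest mean signal. With normexp, 2456 genes changed, 237 of them at least 2-fold.

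**Figure D1:**
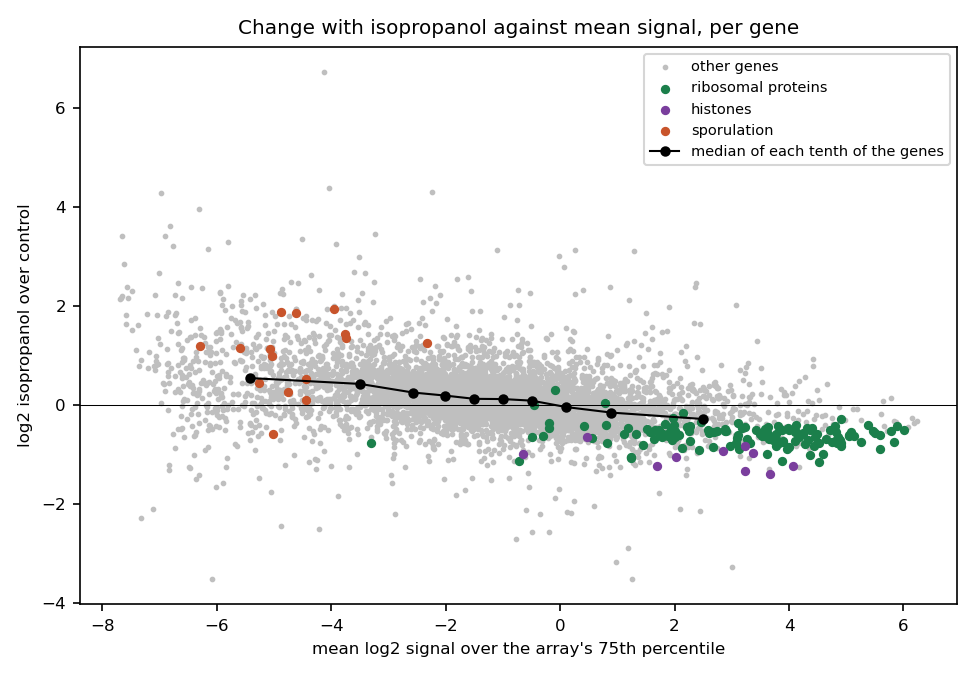
Log2 change with isopropanol (vertical) against mean log2 signal relative to the array's 75th percentile (horizontal) for the 5816 genes tested. Each point is a gene, colours mark 3 gene lists, and black points are medians of bins of 581 or 582 genes, which run from 0.54 at the lowest signals to -0.28 at the highest.

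Spike-in RNAs on the arrays gave another reference. Over 6 spike-in probes measured on all arrays, the 75th percentile of yeast signal rose by 1.15 (log2) relative to the spike-ins. On isopropanol replicate 1 the spike-ins lay 2.61 below the 75th percentile, against 0.88 to 1.11 on the other isopropanol arrays, and without that array the rise was 0.75. Scaled on the spike-ins, the median log2 change of all genes was 1.26, or 0.86 without isopropanol replicate 1, and 99.6% or 98.4% of changed genes were higher. All changes below are relative to each array's 75th percentile and would shift together by 1.15 or 0.75 on the spike-in scale. There the medians of all 37 gene lists below lay above 0, except that of histones without isopropanol replicate 1 (-0.27).

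**Figure D2:**
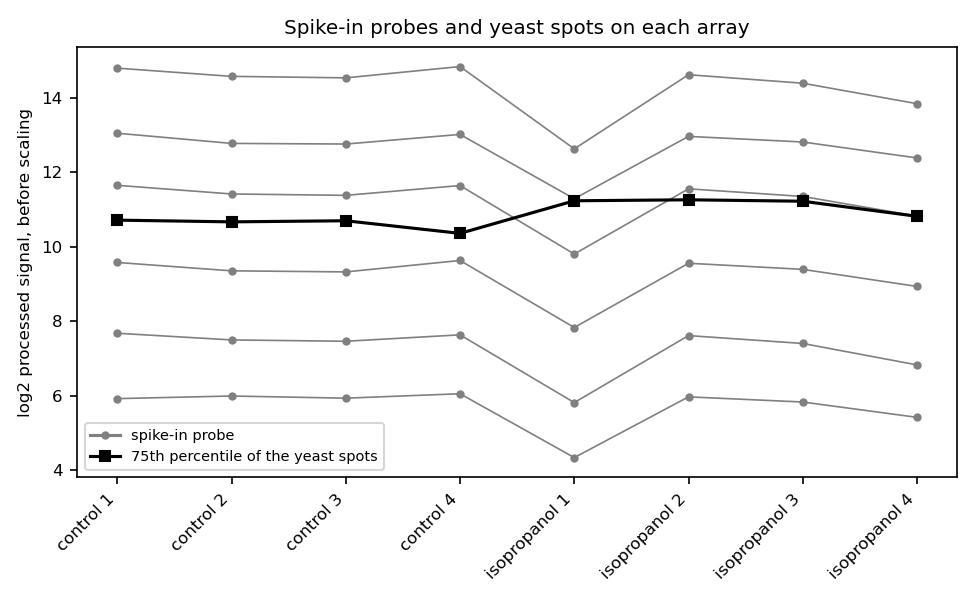
Log2 processed signal before scaling (vertical) of the 6 spike-in probes measured on every array (grey) and the 75th percentile of yeast spots (black) for each of the 8 arrays (horizontal). On isopropanol replicate 1 the mean spike-in signal was 8.62, against 9.70 to 10.5 on the other 7 arrays.

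The 12 increases named by the fixed rule, which went by fitted change, included genes of NAD synthesis, spore formation, membrane transport and arginine synthesis. BNA2 (YJR078W), which encodes the dioxygenase that opens the kynurenine route from tryptophan to NAD, rose 20.7-fold, from -6.22 ± 0.12 to -1.85 ± 0.07 log2 units relative to the 75th percentile (SD, n = 4). LDS2 (YOL047C), a spore wall gene, rose 19.6-fold, from -4.38 ± 0.04 to -0.08 ± 0.13. RSB1 (YOR049C), which encodes a sphingoid base transporter, rose 10.9-fold (log2 3.45, SE 0.06), IRC18 (YJL037W) 10.3-fold (3.36, SE 0.04) and ARG3 (YJL088W), for ornithine carbamoyltransferase, 9.56-fold (3.26, SE 0.08). FIG1 (YBR040W), a mating gene, was well above background on 1 of 4 control arrays and rose at least 7.52-fold, with the other control arrays set no lower than the lowest signal measured above background. In limma these 6 genes had adjusted p between 7.32e-12 and 1.03e-07, and all 4 isopropanol arrays lay above all 4 control arrays. With normexp the rises were smaller, at 1.75 (log2) for BNA2, 3.01 for LDS2, 1.89 for RSB1 and 1.25 for ARG3, and IRC18 (1.11) and FIG1 (0.17) no longer passed.

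For 6 further genes no control array was well above background, so the changes are bounds without an order. ANS1 (YHR126C) was at least 79.3-fold higher (adjusted p = 9.27e-12), and SRL4 (YPL033C) at least 6.74-fold (7.4e-09 adjusted). DAN1 (YJR150C), a cell wall gene of anaerobic cells, was at least 4.73-fold higher, and the sporulation genes SPO75 (YLL005C) and SMA1 (YPL027W) at least 4.24-fold and 3.81-fold. HXT14 (YNL318C), of the hexose transporter family, was at least 2.19-fold higher. Adjusted p for these 4 lay between 1.58e-10 and 2.71e-06. For all 6 genes the adjusted p is that of the fitted change, not of the bound. With normexp, ANS1 passed with a fitted log2 change of 3.13, which is below its bound of 6.31, DAN1, SPO75, HXT14 and SMA1 turned negative without passing the test, and SRL4 no longer passed it.

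The 12 decreases included glucose uptake, cell wall, acetate and citrate genes. HXT2 (YMR011W), a high-affinity glucose transporter, fell 11.4-fold, from 3.01 ± 0.14 to -0.50 ± 0.14 (SD, n = 4). HPF1 (YOL155C), which encodes a cell wall mannoprotein, fell 9.59-fold, from 4.64 ± 0.02 to 1.38 ± 0.10, and its relative CSS1 (YIL169C) 9.04-fold, from 2.56 ± 0.05 to -0.62 ± 0.02. ALD6 (YPL061W), the cytosolic acetaldehyde dehydrogenase, fell 7.39-fold, from 2.62 ± 0.05 to -0.26 ± 0.33, and ACO1 (YLR304C), for aconitase, 5.92-fold, from 1.09 ± 0.03 to -1.48 ± 0.13. HSP30 (YCR021C), a plasma membrane heat shock gene, fell 5.89-fold, MOR1 (YDR366C) 5.70-fold and the alpha-factor gene MF(ALPHA)1 (YPL187W) 5.45-fold (3.54-fold with normexp). ARO10 (YDR380W), a decarboxylase gene of aromatic amino acid breakdown, fell 4.58-fold, ECM13 (YBL043W) 4.56-fold and NRE1 (YIR035C) 4.55-fold. These 11 genes had limma adjusted p between 7.27e-12 and 4.96e-07. VAR1 (Q0140), a mitochondrially encoded ribosomal protein gene, was well above background on 0 of 4 isopropanol arrays. It was at least 2.28-fold lower (adjusted p = 5.52e-06 for the fitted change).

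**Figure D3:**
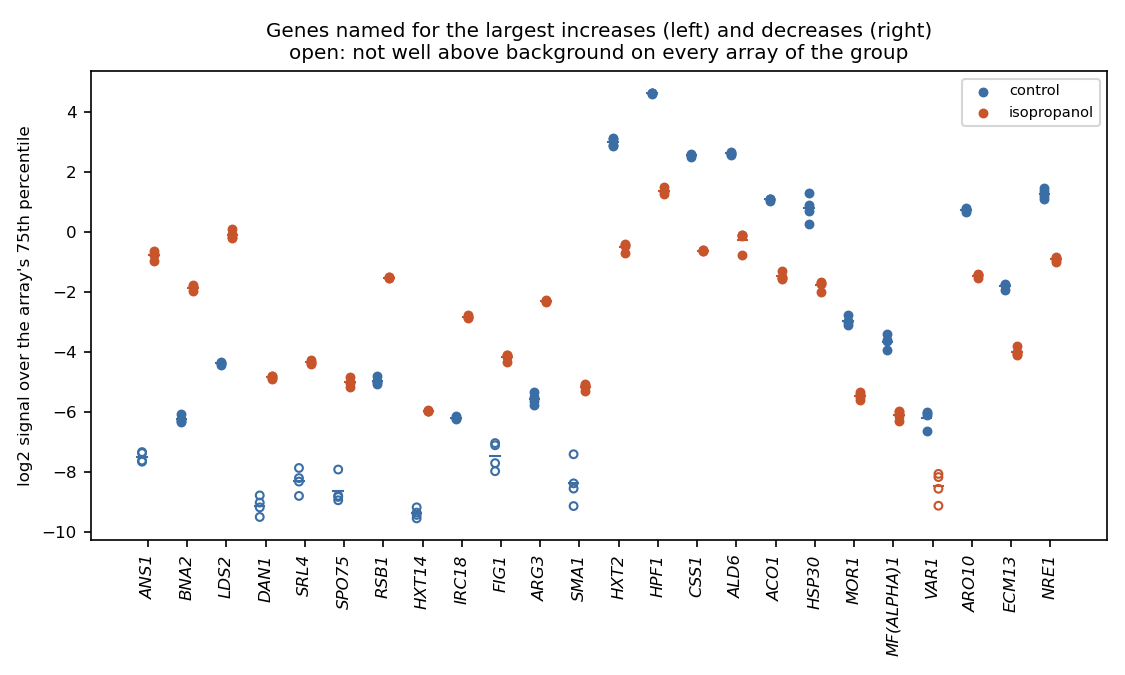
Log2 signal relative to the array's 75th percentile (vertical) on each of the 4 control (blue) and 4 isopropanol (orange) arrays for the 24 named genes (horizontal). Bars are group means and open points mark groups not well above background on every array; the groups of each gene do not overlap.

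Genes of the cytosolic ribosome, of its assembly and of RNA polymerases I and III mostly fell. Of 137 genes in the ribosomal protein list, 134 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone and a median log2 change of -0.59, which turned to 0.56 on the spike-in scale (0.15 without isopropanol replicate 1). The camera adjusted p was 2.36e-30, and adjusted p = 0.193 with an estimated correlation. The list, drawn by name, also holds RPP1 (YHR062C), for a subunit of nuclear ribonuclease P, which fell 1.56-fold and was named after its value was seen. RPL42B fell 2.22-fold (log2 -1.15, SE 0.06) and RPL18B 2.20-fold (-1.14, SE 0.07), followed by RPL43B (2.18-fold) and RPL23B (2.11-fold). Many of these genes have near-identical copies whose probes could share signal. All 59 ribosome biogenesis genes that passed, of 63, were lower (59 adjusted over the list alone). The median of this list was -0.44, or 0.71 on the spike-in scale (0.31 without isopropanol replicate 1). Its camera adjusted p was 3.24e-15, and adjusted p = 0.193 with an estimated correlation. NOP7 fell 2.03-fold, GAR1 1.92-fold, LOC1 1.79-fold and NOP58 1.68-fold. Among 19 RNA polymerase I and III subunit genes, 15 fell and 1 rose, the same adjusted over the list alone. Their median of -0.40 turned to 0.76 on the spike-in scale (0.37 without isopropanol replicate 1). The camera adjusted p was 8.87e-05, and adjusted p = 0.193 with an estimated correlation. RPC17 fell 1.72-fold, RPC34 1.63-fold, RPA34 1.62-fold and RPC25 1.52-fold. Mitochondrial ribosomal protein genes went both ways, with 26 of 69 higher and 9 lower (24 and 9 adjusted over the list alone; median 0.06; camera adjusted p = 0.803). After median centring 6 were higher and 29 lower (median -0.10), and after quantile normalization 12 and 24 (median -0.07), against 5 and 6 (median -0.025) with normexp.

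All 10 histone genes fell, also adjusted over the list alone, with a median of -1.01 that stood at 0.14 on the spike-in scale and at -0.27 there without isopropanol replicate 1. The camera adjusted p was 5.47e-07, and adjusted p = 0.193 with an estimated correlation. HHT1 fell 2.63-fold (log2 -1.40, SE 0.05), HTA2 2.52-fold, HHF1 2.36-fold and HTB2 2.33-fold. G2/M genes rose in 12 of 13 cases, with none lower (12 adjusted over the list alone; median 0.63; camera adjusted p = 0.0128, and adjusted p = 0.193 with an estimated correlation). The kinesin gene KIP2 rose 1.98-fold, MYO1 1.67-fold, the cyclin gene CLB1 1.62-fold and HOF1 1.58-fold, while with normexp KIP2 and MYO1 did not pass and 7 of the 13 were higher, with 0 lower (median 0.42). G1/S and DNA replication genes were split, with 11 of 20 lower and 7 higher, the same adjusted over the list alone (camera adjusted p = 0.0482, and adjusted p = 0.239 with an estimated correlation). Their median was -0.20, or 0.95 on the spike-in scale (0.58 without isopropanol replicate 1). POL30, the replication clamp gene, fell 2.26-fold, RNR1 1.48-fold, CLB6 1.42-fold and RFA2 1.41-fold. The call of this list was lost without control replicate 4, isopropanol replicate 2 or isopropanol replicate 3 (adjusted p = 0.0507, 0.0571 and 0.052), and also after median centring, with normexp and among genes measured on all arrays (0.0523, 0.244 and 0.0545). Over its alternatives other than fry and an estimated correlation, camera adjusted p ran from 0.0295 to 0.244.

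The heat shock, general stress, and trehalose and glycogen lists were called higher. Of 26 heat shock chaperone genes, 20 rose and 4 fell, the same adjusted over the list alone, with a median of 0.47 and a camera adjusted p of 0.0274 (adjusted p = 0.428 with an estimated correlation). SSE2 rose 3.14-fold (log2 1.65, SE 0.06; 2.01-fold with normexp), HSP42 2.70-fold and the mitochondrial chaperone gene HSP78 2.54-fold, against the fall of HSP30. Of 30 general stress genes, 23 rose and 4 fell, the same adjusted over the list alone (median 0.58, or 0.56 with SIP18 at its bound; camera adjusted p = 0.0168, and adjusted p = 0.254 with an estimated correlation). YGP1, for a secreted glycoprotein, rose from -1.52 ± 0.11 to 1.48 ± 0.07 (log2; SD, n = 4), the repressor gene XBP1 rose 3.48-fold and DDR2 3.09-fold. SIP18, not well above background on any control array, was at least 1.25-fold higher. Its limma adjusted p of 0.000139 is for the fitted log2 change of 1.64 (SE 0.25), whereas the bound is 0.32. SIP18 turned negative with normexp, where XBP1 and DDR2 did not pass. Trehalose and glycogen genes rose in 15 of 17 cases and fell in 1, the same adjusted over the list alone (median 0.55; camera adjusted p = 0.0128, and adjusted p = 0.239 with an estimated correlation). NTH2, for a trehalase, rose 2.54-fold, GLG1 1.91-fold and GSY1 1.90-fold, and PGM1 fell 2.06-fold. With normexp GLG1 and GSY1 did not pass, and 7 genes of this list were higher and 1 lower (median 0.25). In the general stress list 10 were then higher and 3 lower (median 0.13), and its call was lost (camera adjusted p = 0.109). Over alternatives other than fry and an estimated correlation, its adjusted p ran from 0.000349 to 0.109.

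Of 33 proteasome genes, 8 rose and 5 fell (4 and 4 adjusted over the list alone; median 0.02; camera adjusted p = 0.588). After quantile normalization 21 rose and 1 fell and the list passed as higher (adjusted p = 0.00873), whereas after median centring 1 rose and 19 fell (median -0.13) and the list did not pass (adjusted p = 0.0575), in a range over alternatives of 0.00873 to 0.782. With normexp 5 were higher and 2 lower (median 0.06). PUP1 rose 1.34-fold, RPN2 and SEM1 1.18-fold each, the last pair not after median centring, and PRE3 fell 1.28-fold. Of 18 ubiquitin system genes 14 rose and 1 fell, the same adjusted over the list alone (median 0.25; camera adjusted p = 0.0419, and adjusted p = 0.193 with an estimated correlation), a call lost after median centring and without control replicate 3 and isopropanol replicate 1 together (adjusted p = 0.075 and 0.0553, in a range of 0.00159 to 0.234). After median centring 8 of these were higher and 2 lower (median 0.09), and with normexp 8 and 1 (median 0.18). Of 15 autophagy genes 13 rose and 2 fell, the same adjusted over the list alone (median 0.42, but -0.09 with normexp; camera adjusted p = 0.0274, and adjusted p = 0.193 with an estimated correlation), a call lost after quantile normalization and with normexp (adjusted p = 0.189 and 0.526, the latter the highest of its alternatives, which began at 0.00908). After quantile normalization 8 autophagy genes were higher and 3 lower (median 0.15), and with normexp 2 and 2. Antioxidant genes went both ways, with 11 of 24 higher and 8 lower, and endoplasmic reticulum folding genes with 6 of 17 higher and 4 lower, both the same adjusted over the list alone (medians 0.05 and 0.10; camera adjusted p = 0.633 and 0.906). After median centring 9 and 11 antioxidant genes were higher and lower (median -0.10), and 6 and 7 folding genes (median -0.06). With normexp 7 antioxidant genes were higher and 8 lower.

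Membrane and wall genes changed in several directions. Of 16 multidrug resistance genes, 12 rose and 2 fell, the same adjusted over the list alone (median 0.76; camera adjusted p = 0.0206, and adjusted p = 0.198 with an estimated correlation). Beside RSB1, the acyltransferase gene ICT1 rose 4.06-fold (log2 2.02, SE 0.07) and the drug pump gene PDR5 2.82-fold, whereas PDR12, for a weak acid pump, fell 2.87-fold. Of 27 cell wall genes, 18 rose and 6 fell, the same adjusted over the list alone (median 0.58; camera adjusted p = 0.0289, and adjusted p = 0.239 with an estimated correlation). PIR3 rose 6.90-fold (log2 2.79, SE 0.05), TIR1 5.25-fold and the glucan synthase gene GSC2 4.32-fold, beside DAN1. Ergosterol genes were lower in 9 of 24 cases and higher in 5 (9 and 3 adjusted over the list alone; median -0.05, but 0.01 with normexp), and the list did not pass (camera adjusted p = 0.0507). After median centring 15 were lower and 0 higher (median -0.21), and after quantile normalization 8 and 8 (median 0.05). ERG2 fell 1.81-fold, HMG1 1.71-fold, ERG24 1.54-fold and ERG10 1.49-fold. The ergosterol list passed without control replicate 1, 2 or 3 or isopropanol replicate 4 (adjusted p = 0.0421, 0.0416, 0.0442 and 0.0371) and without control replicate 3 and isopropanol replicate 1 together (0.0464). It also passed after median centring (adjusted p = 0.00842), with series matrix values (0.0384), without the filter on dim probes (0.0483), with flagged spots kept (0.0377) and with trended robust moderation (0.0473), in a range of 0.00842 to 0.98 over alternatives. Fatty acid synthesis genes (7 of 13 higher, 6 lower, the same adjusted over the list alone; median 0.18; camera adjusted p = 0.498) and phospholipid genes (8 of 19 higher, 4 lower, and 8 and 3 adjusted over the list alone; median 0.05, but -0.11 after median centring and -0.06 with normexp; camera adjusted p = 0.588) had no call. After median centring 3 fatty acid genes were higher and 6 lower (median 0.02), and 8 and 8 phospholipid genes, while with normexp 5 phospholipid genes were higher and 0 lower. Vacuolar ATPase genes were lower in 9 of 19 cases and higher in 3, the same adjusted over the list alone (median -0.14; camera adjusted p = 0.061). After quantile normalization 5 were lower and 5 higher (median 0.02), after median centring 14 and 1 (median -0.30), and with normexp 5 and 2 (median -0.09). That list passed after median centring and without control replicate 2 (adjusted p = 0.025 and 0.0416, in a range of 0.025 to 0.882).

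Of the amino acid lists, that of the Gcn4 type was called higher. Of 35 amino acid synthesis genes of the Gcn4 type, 25 rose and 5 fell, the same adjusted over the list alone (median 0.31; camera adjusted p = 0.0147, and adjusted p = 0.239 with an estimated correlation). After median centring 18 were higher and 8 lower (median 0.15). The members with the largest changes all belong to arginine synthesis: ARG1 rose 8.71-fold (log2 3.12, SE 0.04), ARG4 3.71-fold and CPA1 2.57-fold, beside ARG3. Of 21 sulfate and methionine genes, 15 rose and 4 fell, the same adjusted over the list alone (median 0.48), but the list did not pass (camera adjusted p = 0.0535). STR3 rose 4.75-fold, the regulator gene MET28 4.69-fold, MET2 2.98-fold and MET13 2.67-fold, of which MET28 alone passed with normexp (3.11-fold). There 8 of the list were higher and 3 lower (median 0.28). The list passed without control replicate 1 or 2 (adjusted p = 0.0478 and 0.0439), after quantile normalization (0.00561) and after median centring (0.025). It also passed without the filter on dim probes (adjusted p = 0.0417), among genes measured on all arrays (0.0481) and with trended robust moderation (0.0473), in a range of 0.00561 to 0.0617. With an estimated correlation its camera adjusted p was 0.193. Aromatic amino acid genes went both ways, with 7 of 15 higher and 6 lower, the same adjusted over the list alone (median 0.05; camera adjusted p = 0.359), while after median centring 5 were higher and 7 lower (median -0.11). ARO9, a transaminase gene, fell 3.69-fold beside ARO10, TRP1 fell 1.42-fold and ARO3 rose 1.61-fold. Nitrogen catabolite genes were higher in 13 of 19 cases and lower in 5, the same adjusted over the list alone (median 0.30; camera adjusted p = 0.359), and with normexp 5 were higher and 5 lower (median -0.09).

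In carbon metabolism, 10 of 11 gluconeogenesis and glyoxylate genes rose and 1 fell, the same adjusted over the list alone (median 0.83; camera adjusted p = 0.0129, and adjusted p = 0.193 with an estimated correlation). CIT2, for peroxisomal citrate synthase, rose 5.54-fold (log2 2.47, SE 0.05), MLS1 2.81-fold, the isocitrate lyase gene ICL1 2.52-fold and the lactate transporter gene JEN1 2.50-fold. With normexp MLS1 turned negative, JEN1 did not pass and the list lost its call (adjusted p = 0.216, in a range of 0.000683 to 0.216), with 3 genes higher and 1 lower (median 0.12). Tricarboxylic acid cycle genes were split, with 4 of 10 higher and 3 lower, the same adjusted over the list alone (median -0.06, but 0.06 after quantile normalization; camera adjusted p = 0.322), and 3 were higher and 6 lower after median centring (median -0.22). IDH2 fell 2.65-fold and IDH1 2.29-fold beside ACO1, and CIT1 rose 1.82-fold. Of 35 nuclear-encoded respiratory genes 15 rose and 8 fell, the same adjusted over the list alone (median 0.08; camera adjusted p = 0.803), whereas 8 were higher and 14 lower after median centring (median -0.08). NDE1, for an NADH dehydrogenase, fell 3.43-fold and the cytochrome c gene CYC1 2.79-fold, while NDI1 rose 1.71-fold (not with normexp) and QCR2 1.60-fold. Hexose transport genes were higher in 5 of 12 cases and lower in 4 (4 and 4 adjusted over the list alone; median 0.02; camera adjusted p = 0.414). After median centring 4 were higher and 6 lower (median -0.14), after quantile normalization 5 and 6 (median -0.11), and with normexp 2 and 4 (median -0.14). Beside HXT2, the near-identical HXT7 and HXT6, whose probes could share signal, fell 2.60-fold and 2.32-fold, and MTH1 rose 3.11-fold but did not pass with normexp. Of 18 glycolysis and fermentation genes, 5 rose and 8 fell, the same adjusted over the list alone (median -0.04; camera adjusted p = 0.359), whereas 13 rose and 1 fell after quantile normalization (median 0.26, adjusted p = 0.00651, in a range up to 0.76) and 4 and 3 were higher and lower with normexp. PDC6, for a minor pyruvate decarboxylase, rose 7.97-fold (2.72-fold with normexp), TDH1 4.03-fold and ENO1 2.47-fold, and HXK2 fell 1.70-fold. Alcohol and aldehyde dehydrogenase genes were higher in 9 of 18 cases and lower in 4 (8 and 4 adjusted over the list alone; median 0.18; camera adjusted p = 0.588), but in 7 and 7 after median centring (median 0.03) and 5 and 3 with normexp. ADH5 rose 3.72-fold, ADH2 2.21-fold and GRE2 1.84-fold, against the fall of ALD6. Osmotic and glycerol genes (10 of 14 higher, 2 lower; median 0.21; camera adjusted p = 0.309, but 0.0441 after quantile normalization, in a range up to 0.336) and peroxisomal oxidation genes (9 of 14 higher, 1 lower; median 0.21; camera adjusted p = 0.136), with the same counts adjusted over each list alone, had no call. Of the osmotic genes 6 were higher and 3 lower after median centring (median 0.05), and 5 and 2 with normexp (median 0.16). Of the peroxisomal genes 4 were higher and 8 lower after quantile normalization (median -0.20), and 0 and 1 with normexp (median -0.30).

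Genes of meiosis and mating, at low signal in these diploid cultures, were mostly higher, but not with normexp. Of 15 sporulation genes, 13 rose and 1 fell, the same adjusted over the list alone (median 1.15; camera adjusted p = 0.00934, and adjusted p = 0.193 with an estimated correlation). REC8 rose 3.83-fold (log2 1.94, SE 0.05), SPO19 3.70-fold, SPS1 3.63-fold and DIT1 2.71-fold. Of 16 haploid and mating genes, 14 rose and 1 fell, the same adjusted over the list alone (median 0.67; camera adjusted p = 0.0152, and adjusted p = 0.224 with an estimated correlation). FUS1 rose 2.47-fold, the a-factor gene MFA1 2.46-fold and HO, measured on 3 of 4 control arrays, 2.77-fold, against the fall of MF(ALPHA)1. Other alpha-specific genes rose, STE3 1.98-fold and MF(ALPHA)2, measured on 2 of 4 control arrays, 1.85-fold (both named after their values were seen), but neither passed with normexp (0.13 and -0.81). The mating list lost its call after quantile normalization (adjusted p = 0.273), with 9 genes higher and 4 lower (median 0.18). With normexp 1 sporulation gene was higher and 1 lower, and 0 and 1 mating genes, the medians of both lists turned negative (-0.37 and -0.18) and neither passed (adjusted p = 0.98 and 0.634, the highest of the alternatives, which began at 1.17e-05 and 0.00428). There HO and MFA1 also turned negative, and REC8, SPO19, SPS1, DIT1 and FUS1 did not pass. Since the normexp offset draws genes near background down, these values alone do not decide whether these genes rose. Iron uptake genes (13 of 18 higher, 4 lower, and 14 and 4 adjusted over the list alone; median 0.30; camera adjusted p = 0.103) and phosphate genes (2 of 15 higher, 8 lower, the same adjusted over the list alone; median -0.18; camera adjusted p = 0.061) had no call. After quantile normalization 8 iron genes were higher and 5 lower (median 0.08), and 4 and 5 phosphate genes (median -0.04), and with normexp 4 and 3 (median 0.04) and 1 and 4 (median -0.15). The phosphate list passed without control replicate 1 or 2 (adjusted p = 0.0485 and 0.0439, in a range of 0.0439 to 0.894).

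In all, 17 of 37 lists passed camera with its preset correlation, 12 higher and 5 lower, and 0 passed with a correlation estimated for each list, where 8 had an unadjusted p under 0.05. In 7 lists, none of them past the threshold, the median and the camera test differed in sign. On the spike-in scale 11 lists passed: the heat shock, trehalose and glycogen, ubiquitin, autophagy, G1/S, G2/M and mating lists lost their calls (adjusted p = 0.0598 to 0.228) and the sulfate and methionine list gained one (0.0235). The lists were fixed before the data were examined, but the 24 whose members are named were picked from the 37 after a look at their results.

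**Figure D4:**
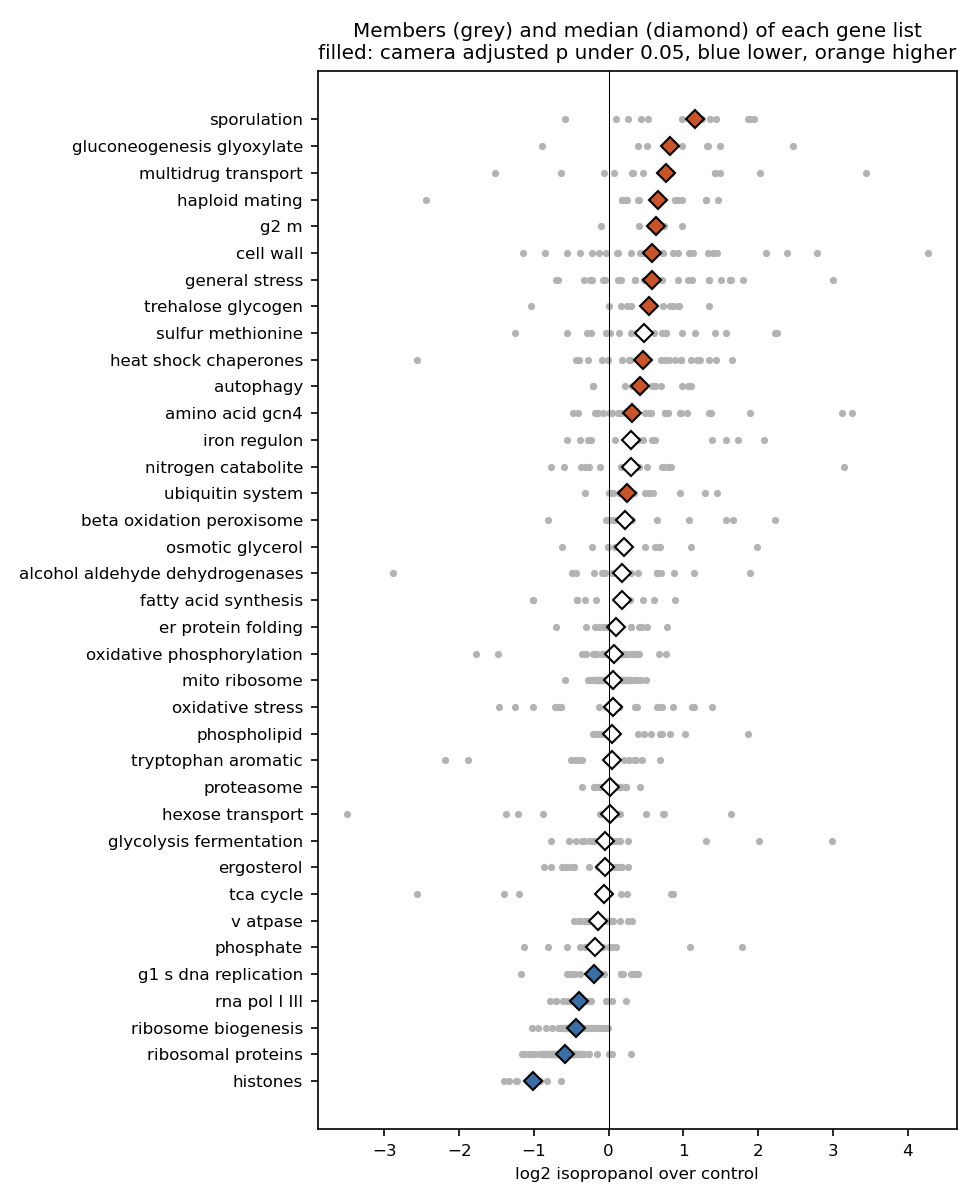
Log2 change with isopropanol (horizontal) of the members (grey points) and the median (diamond) of the 37 gene lists (vertical). Filled diamonds passed camera with its preset correlation, with medians from -1.01 for histones to 1.15 for sporulation, and 0 lists passed with an estimated correlation; after quantile normalization the proteasome and glycolysis lists were called higher.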

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

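The tests of the trend with signal and of the meiosis and mating lists were chosen after these results were seen; the splits of the arrays were planned. A sample was picked out where it stood apart from the other 3 of its group by Dixon's test, which happens by chance in about 1 in 20 groups. Of 220 groups of 4 values looked at, 17 stood out, where chance gives 11. The 75th percentile of signal was 1312 on control replicate 4, against 1625 to 1678 on the other controls, and 1802 on isopropanol replicate 4, against 2384 to 2449. The spike-ins lay at -2.61 relative to the 75th percentile on isopropanol replicate 1, against -1.11 to -0.88. On control replicate 4, CLB1 stood at 0.84 (others up to 1.01), MET28 at -3.25 (others -3.20 to -3.19) and YGP1 at -1.36 (others -1.59 to -1.55). Control replicate 2 stood apart for VAR1 at -6.63 (others -6.08 to -6.00) and ADH2 at -2.47 (others -2.33 to -2.31), and control replicate 1 for CIT1 at -0.27 (others 0.11 to 0.18). On isopropanol replicate 1, HSP30 was at -1.99 (others -1.73 to -1.68) and RNR1 at 0.97 (others 1.11 to 1.13). On isopropanol replicate 2, ERG2 was at 2.39 (others 2.29 to 2.30), ADH2 at -1.07 (others -1.29 to -1.26) and MET2 at -2.38 (others -2.33). Isopropanol replicate 4 stood apart for ARO10 at -1.53 (others -1.42 to -1.41), HXT2 at -0.70 (others -0.45 to -0.40) and ALD6 at -0.76 (others -0.12 to -0.09).

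Of 35 splits of the 8 arrays into 4 and 4, 1, the real split, gave as many changed genes (4525, highest other 0). The same held for 2-fold genes (551, highest other 0). Every other split mixes arrays of both slides, which puts the group difference into its spread, so low counts were likely there. The counts thus belong to this grouping of the arrays, but the splits cannot say what made the groups differ. For gene lists, 1 split of 35 gave as many (17), but another split gave 15. Splits that keep 3 arrays of a group together carry part of the real contrast, and among the 18 splits with 2 arrays of each group on each side the highest was 6 lists. With its preset correlation camera can therefore call lists where no gene passes. The slide cannot be told apart from the treatment, since 0 slides held arrays of both groups.

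Low-signal genes rose and high-signal genes fell. A compressed signal scale on the isopropanol slide would raise dim spike-ins over bright ones by about as much as genes of the same signals, for which the difference was 0.74 (log2); the 2 dim spike-ins rose over the 3 bright ones by 0.0447 (SE 0.0506). A higher unspecific background on the isopropanol arrays would show in the 77 negative control spots, whose median differed by 0.375 intensity units (SE 0.375), while the 582 genes of lowest signal gained a median of 29.7 units of processed signal. Both values argue against these explanations, within limits. The dim spike-ins had control means of 5.98 and 7.57 (log2 processed signal), above the median of 4.90 for the genes of lowest signal. Compression at those lowest signals was therefore not tested. The gain of 29.7 units was taken before scaling, so it also holds the higher signal of the isopropanol arrays as a whole. A slide effect on the labelled yeast RNA alone, and an effect of isopropanol, stay open, as do the scaling and background correction. The filter on dim probes kept 144 genes above background on all isopropanol but not all control arrays, against 20 the other way. Its part in the trend was not tested.

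Sporulation and mating genes were higher in a diploid culture. If the general rise of low-signal genes were the whole cause, their medians would lie among random lists of the same mean signals. The sporulation median of 1.15 was at percentile 99.82 of such lists (middle 95%: 0.09 to 0.87). After quantile normalization and median centring it was at 99.85 and 99.8. With normexp it was -0.37, at percentile 81.62 (-0.66 to -0.28). Such lists were lower there, so normexp gives no general rise to test. After quantile normalization such lists did not rise as a group either (-0.43 to 0.38). On the reported scale and after median centring (0.99, against -0.07 to 0.705) the sporulation median lay above the middle 95%. It thus stood apart from genes of the same signals on those scales, while normexp cannot decide the question. This test first used the reported scale alone, which counted against the general rise, and the other scalings were added after its result was seen. The mating median of 0.67 was at percentile 90.55 (0.10 to 0.81) and within the middle 95% under the same 3 alternatives. It thus did not stand apart from genes of the same signals on any of these scales. After quantile normalization and with normexp such lists did not rise as a group (-0.35 to 0.35 and -0.57 to -0.15). There the test says nothing of a general rise. Alpha haploid cells in the isopropanol cultures would raise all 3 alpha-specific genes examined, but MF(ALPHA)1 fell by 2.45 while MF(ALPHA)2 rose by 0.89 and STE3 by 0.98 (log2), which leaves that explanation open. This test first rested on the fall of MF(ALPHA)1 alone, which counted against such cells; it was widened to the 3 genes after its result was seen, since isopropanol may itself lower 1 gene. The slide and a response to isopropanol stay open for both lists.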

How the results depend on the processing

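The spike-in settings and the pair of arrays left out together were chosen after seeing the data. Changed genes numbered 4025 to 4967 and 2-fold genes 416 to 605 under the alternatives set in advance other than normexp and the size criteria, and 4358 to 4547 and 542 to 559 with each array left out, where gene lists past the threshold numbered 16 to 21. Without control replicate 3 and isopropanol replicate 1 together, 4229 and 548 genes passed. With normexp, 2456 genes changed, 237 at least 2-fold, and 11 lists passed. There 36 of 111 named genes moved by over 1.5-fold, all to values nearer 0 or of opposite sign, and 10 of the 36 still passed. Normexp adds an offset of 50 to every signal before scaling to the array's 75th percentile. That percentile of processed signal averaged 1568 on control and 2260 on isopropanol arrays. A constant offset therefore lies lower on the isopropanol scale, which draws genes near background below 0. Such values alone do not decide whether these genes rose. The size of this effect on each gene was not tested. Values turned to -0.15 for DAN1, -0.32 for SPO75, -0.60 for HXT14, -0.41 for SMA1, -0.97 for SIP18, -0.16 for MLS1, -0.59 for HO and -0.55 for MFA1, and 20 other named genes no longer passed. As a median over that of all genes, the mating list turned to -0.10, the sporulation list to -0.29 and the autophagy list to -0.00637. Among lists without a call, that of peroxisomal oxidation turned to -0.22, and others also changed sign. A 1.5-fold minimum gave 1434 genes and treat against 1.5-fold 914, by their own construction. At an adjusted p under 0.01, 5 lists passed; with an estimated correlation 0, with fry 33 and with mixed fry 37. Relative to the median of all genes, the proteasome list turned to 0.17 and the glycolysis list to 0.28 after quantile normalization, for which the cause was not tested. On the reported scale the glycolysis list stood at -0.16 by that measure, but fry took it as moving up. Its mean log2 change was 0.21, beside a median of -0.04. No named gene lost its call or direction when any array was left out. These genes were picked from the same data among those that passed, so this is no independent test of their calls. Of 296 list calls 12 changed, 3 lost and 9 gained.

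Scaled on the spike-ins, 4154 genes changed at least 2-fold (2253 without isopropanol replicate 1), since all genes shift together, and 11 lists passed (11 without it), for which the cause was not tested. In that scaling 22 named genes turned from lower to higher: RPL18B 0.0135, RPL43B 0.0242, RPL23B 0.0719, NOP7 0.13, GAR1 0.21, LOC1 0.31, NOP58 0.40, RPC17 0.37, RPC34 0.45, RPA34 0.45, RPC25 0.55, RNR1 0.59, CLB6 0.65, RFA2 0.65, PGM1 0.11, PRE3 0.80, TRP1 0.64, HXK2 0.39, ERG2 0.29, HMG1 0.38, ERG24 0.53 and ERG10 0.58. Without isopropanol replicate 1, 11 did: NOP58 0.0927, RPC34 0.0411, RPA34 0.11, RPC25 0.15, RNR1 0.22, CLB6 0.22, RFA2 0.27, PRE3 0.37, TRP1 0.24, ERG24 0.14 and ERG10 0.19. None of these values passed the test, and 14 and 10 other named genes lost their calls without turning.

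The replicate numbers do not pair the arrays: same-numbered arrays' deviations correlated at 0.04, -0.16, -0.01 and -0.16, and no array correlated best with its own number. With the replicate number as a block 4397 genes changed and 551 at least 2-fold, 17 lists passed, and no call of a list or named gene changed. With scan as a random block, where control replicate 3 was scanned apart, 4967 genes changed, the top of the range above, but the estimated correlation within scans was negative (-0.21), so this count corrects for no shared scan effect. A slide block was not run, since each slide holds 1 group. Signal over background limits dim genes: 45 of the 436 genes at least 2-fold higher had no control array above background, and with such genes at their bounds 532 of the 551 stayed at least 2-fold.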

Other observations

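The lists, tests and named genes in this part were all chosen after the values were seen. Genes of NAD synthesis from tryptophan were higher: of 7 BNA genes, 6 rose and 1 fell, with a median log2 change of 1.14. Besides BNA2, BNA1 rose by 2.26 (SE 0.08), BNA4 by 1.32 (SE 0.04), BNA5 by 1.14 (SE 0.05) and BNA6 by 1.02 (SE 0.04), while BNA7 changed by -0.36 (SE 0.05). The camera p was 0.0105, and 0.0809 with an estimated correlation. Of 8 vitamin B6 genes 7 rose (median 1.45, or 1.27 with bounded genes at their bounds; camera p = 0.00405, and p = 0.0248 with an estimated correlation), with SNZ1 at 2.24 (SE 0.05) and SNO1 at 2.63 (SE 0.12). With normexp that median was 0.31 and 2 of the 8 rose. SNO2 and SNO3, not well above background on any control array, were at least 2.22-fold and 3.12-fold higher (adjusted p = 0.00268 and 5.34e-10 for the fitted changes).

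Genes of the TIR, DAN and PAU families, many of them known from anaerobic cells, moved together: 29 of 30 rose and 1 fell, with a median of 1.09 (camera p = 6.34e-09, and p = 0.12 with an estimated correlation). TIR1 rose by 2.39 (SE 0.07), DAN4 by 1.64 (SE 0.05) and PAU2 by 1.32 (SE 0.04), while TIR3 changed by -0.22 (SE 0.08). PAU genes are near-identical copies whose probes could share signal. The median of the list lay above those of all 10000 random lists of the same mean signals (middle 95%: -0.02 to 0.30).

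Mitochondrially encoded genes were lower: 14 of 15 fell, with a median of -1.48, or -1.23 with VAR1 at its bound (camera p = 3.15e-07, and p = 0.0546 with an estimated correlation). The counts, the comparison with random lists and the test at the preset correlation treat the 15 genes as separate. Whether some of them share a transcript was not examined. AI5_ALPHA fell by 2.17 (SE 0.09), COB by 1.94 (SE 0.19), COX1 by 1.82 (SE 0.11) and OLI1 by 0.59 (SE 0.08). On the spike-in scale the median was -0.33, with 2 lower and 1 higher, or -0.66 without isopropanol replicate 1, with 9 lower and 1 higher. The general trend with signal would put the median among random lists of the same mean signals, but it was at percentile 0 (middle 95%: -0.05 to 0.58), and also after quantile normalization, after median centring and with normexp, which argues against that trend. Fewer mitochondrial genomes, lowering every transcript alike, would give about the same change in each. The 95% intervals of 9 of the 14 measured in both groups left out their median of -1.35. The measured changes thus differed by more than the spread between arrays. Those intervals leave out differences between probes in response, so the count does not decide whether the loss was even. VAR1, which has only a bound, was left out of this count after its first run. A lower yield of transcripts without long poly(A) tails in labelling was not tested, and may, like the slide and the treatment, account for the change.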
